A study of Malus spectabilis with 18 samples.

How the data were processed

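Gene expression was measured by RNA sequencing in stems, leaves and receptacles of grafted trees of the apple Malus spectabilis 'Bly114' and of a more-branching mutant (MB) selected from it. The receptacle is the part of the flower stalk that carries the floral organs. The series holds 18 samples in 6 groups of 3. Messenger RNA was selected with oligo(dT) beads and sequenced on an Illumina HiSeq instrument, per the labels' protocols. Groups follow the titles, source names and genotype tags. In stems these conflict, because the source names set a scion called WB apart from 'Bly114' while the genotype tag reads wild type for both, so the stem groups are named here by their scions. The source names give WB as the scion of the MB leaves and MB receptacles as well, which ties the name WB to the mutant. The source names of the wild-type receptacles give a cultivar number other than that of the remaining wild-type samples. The source names number the WB scions from 1 to 3 in each tissue, and those of the other groups carry no number. Whether the 3 libraries of a group came from separate plants is not stated, so p-values measure only the spread between these libraries, which may be technical. No label gives a sequencing batch, date or lane, so none could be examined.

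The values are FPKM (fragments relative to gene length and to a total for the library), deposited by the authors as a table of the 12 stem and leaf libraries and another table of receptacle libraries. HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2 are named in the submitters' processing notes. The role of each tool, the genome build, the annotation and the use of strand are not given in the sources used here, so genes that overlap, or that share reads with a near-identical copy, carry an uncertainty that could not be measured. The tables were normalized separately and were never tested together. The table of receptacles holds 3 columns whose names match no label, and these 3 columns were not used in any step. The planned comparison of MB with wild-type receptacles was therefore not made. The names of the 3 columns of MB leaves show the group and end in a number, but they match no sample title in full, so the columns were not tied to single samples and entered the tests as replicates of the group. The files do not pair the gene identifiers with names and no annotation was used here, so the 28 gene lists fixed in advance (strigolactone, cytokinin, auxin, branching regulators, cell-type markers and others) could not be tested, and genes are given by identifier without a function or a position.

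Depth was recovered from the FPKM values of the stem and leaf table. Low values of a gene are whole multiples of what 1 read is worth, which depends on the gene's length and on the denominator of the library. Of 46558 genes, 6085 were at 0 in every library and 1420 were above 0 in 1 library only. All of the remaining 39053 genes gave whole reads within a tolerance of 0.001 read, and 99.8% of the lengths came out whole within 0.01 base. On simulated tables of 12000 genes the same steps returned every read for 99.98% of genes. Libraries held 15648626 to 17364466 reads in genes. The denominators behind the deposited FPKM were 0.789 to 1.22 times these totals, with 1.05 to 1.06 in 'Bly114' stems, 1.20 to 1.22 in WB stems, 0.789 to 0.847 in wild-type leaves and 0.887 to 0.907 in MB leaves. The authors' FPKM are thus scaled on a quantity other than the reads in genes, and this quantity differed between groups. At the median gene length of 1389 bases, 1 FPKM stood for 17.3 to 29.3 reads, depending on the library. Limits for genes without reads use 3 reads per library and cover counting error only. The receptacle values do not sit on such shared steps, so the depth of those libraries is unknown.

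Differences were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), in 1 model of the 4 stem and leaf groups with a spread estimated over all 12 libraries and a trend of the spread with expression. A gene was tested if its FPKM was at least 1 in at least 3 libraries, which left 31021 genes. Tests are two-sided, p-values are adjusted by Benjamini-Hochberg within each comparison, and a gene is called changed at an adjusted p under 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. The comparisons were WB with 'Bly114' stems, MB with wild-type leaves, the difference between these differences (the interaction), and wild-type leaves with 'Bly114' stems. The overlap of calls was tested with a one-sided Fisher's exact test. The groups, tests, filter, settings varied and the rule for named genes were fixed before the data were examined. Named genes are the 2 with the largest rise and the 2 with the largest fall in a comparison, among genes with an adjusted p under 0.05, a mean of at least 5 FPKM in the higher group and no overlap between the libraries of the groups. For the interaction, the highest of the 4 group means was used, and non-overlap was required only in the tissue with the larger difference. The rule fixed in advance did not spell out this form.

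Before use, the fits were tested on simulated data with fold changes of 1.5, 2 and 4, over 5 draws for each comparison. Every simulated gene had the same dispersion of 0.00546, the median of well-covered genes in WB stems, and few genes were changed. Of the genes changed 2-fold, 91.3% were recovered for stems (30078 genes in the step), 93.1% for leaves (30082 genes), 75.8% for the interaction (30077 genes) and 91.3% for leaf against stem (30068 genes). Of those changed 1.5-fold, the shares were 64.8%, 62.4%, 25.4% and 64.5% in the same order. False calls made up 3.2% of the calls for stems, 9.79% for leaves, 5.07% for the interaction and 7.1% for leaf against stem, so the rate ran above the nominal 5% in leaves, in leaf against stem and slightly in the interaction. Libraries of a group were compared over genes by chi-square on the recovered reads. The statistic per degree of freedom was 2.83 to 19.3, above sampling noise in every pair, so no library was counted as another one sequenced again. Separate libraries from 1 plant could exceed sampling noise too. It reached 19.3 among 'Bly114' stems and 16.5 among wild-type leaves, against 9.42 among WB stems, which set the simulated spread, and 5.96 among MB leaves. The simulated rates may therefore differ from those in the data.

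Alternatives fixed in advance were pseudocounts of 0.1 and 0.01, no filter on low values, a mean of at least 5 FPKM, rescaling by a trimmed mean, quantile normalization, limma without the trend or with a robust spread, a fold of at least 2 beside the adjusted p, each library left out in turn, a replicate block, and the libraries of 1 tissue alone. After the data had been seen, limma's voom on the recovered reads, FPKM rebuilt on the reads in genes, and a fit without 'Bly114' stem library 3 and wild-type leaf library 1 were added. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.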

Results

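Transcript levels of 46558 annotated apple genes were available for stems and leaves of 2 kinds of scion and for receptacles of the mutant. The mutant, MB, arose as a branch with natural variation on a wild-type 'Bly114' tree and branches more than its parent, and both were grafted on Malus robusta. Each of the 4 stem and leaf groups held 3 libraries, with 15648626 to 17364466 recovered reads in genes per library. Between 27092 and 29113 genes reached at least 1 FPKM in a library. Of the 31021 genes tested, the files pair none with a name, so single genes are given by identifier.

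Tissue and scion separated the 12 libraries along different axes. The first principal component held 62.6% of the variance and separated stems from leaves, and the second held 24.97% and separated 'Bly114' and wild-type libraries from WB and MB libraries. Pearson correlations across genes ran from 0.969 to 0.989 within groups, from 0.886 to 0.913 between WB and 'Bly114' stems, and from 0.875 to 0.901 between MB and wild-type leaves. Along the first component, wild-type leaf library 1 had a score of 64.7, against 97.1 and 102.4 for libraries 2 and 3. 'Bly114' stem library 3 had a score of -118.8, against -89.8 and -96.7 for libraries 1 and 2.

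**Figure D1:**
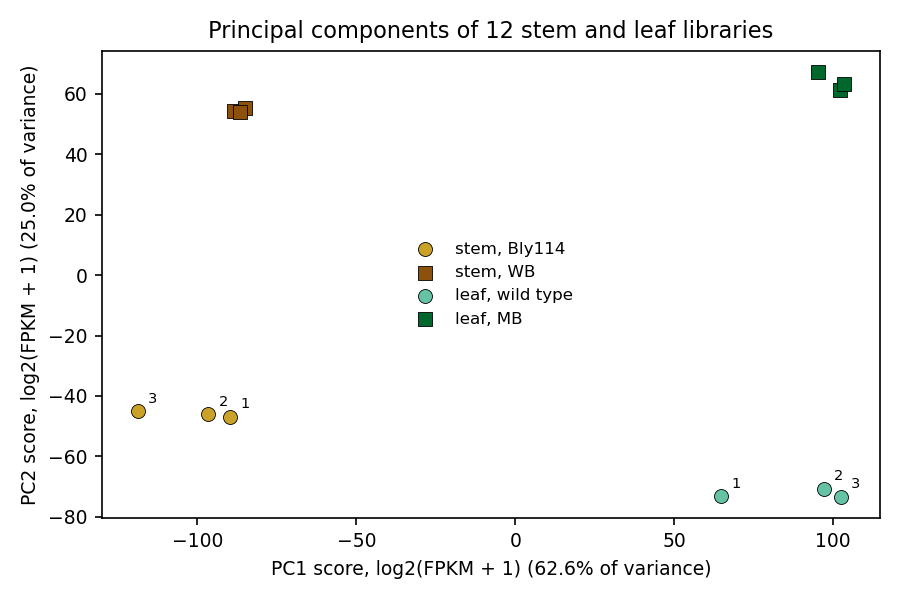
Scores of the 12 stem and leaf libraries on the first (x axis, 62.6% of variance) and second (y axis, 24.97%) principal components of log2(FPKM + 1), 1 point per library, with replicate numbers printed for 'Bly114' stems and wild-type leaves. On the second component, 'Bly114' and wild-type libraries lie between -73.3 and -45.1, and WB and MB libraries between 54.0 and 67.2.

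The comparison of WB with 'Bly114' stems asks which genes differ between the scions in the organ that carries the buds. In WB stems 5361 genes rose and 6168 fell, together 37.2% of the genes tested, with a median absolute log2 fold change of 0.69 among them. Changes of at least 4-fold were found for 215 genes that rose and 328 that fell, and of at least 16-fold for 13 and 36. MD11G1082600 rose from 1.30 ± 1.05 FPKM in 'Bly114' stems to 229 ± 26.6 in WB stems (SD, n = 3 each; log2 fold change 6.73, SE 0.24, limma adjusted p = 1.3e-09). MD11G1204100 had 1 read in 1 of the 3 'Bly114' stem libraries and rose to 50.2 ± 10.3 FPKM in WB stems (log2 fold change 5.60, SE 0.16, limma adjusted p = 2.3e-10). The largest falls were those of MD01G1208700, from 900 ± 150 to 5.15 ± 0.942 FPKM (log2 fold change -7.19, SE 0.14, limma adjusted p = 2.0e-11), and of MD06G1201600, from 262 ± 58.3 to 0.872 ± 0.26 FPKM (log2 fold change -7.12, SE 0.17, limma adjusted p = 5.5e-11). On the FPKM scale the 2 falls were 174.8-fold and 299.9-fold. For 15728 genes, 50.7% of those tested, the libraries of both groups did not overlap, where chance gives 10%.

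The balance between rises and falls in stems moved with abundance and with the scaling. Among genes with a mean under 5 FPKM, 1703 rose and 1240 fell, whereas 3101 rose and 4046 fell among those at 5 to 50 FPKM and 557 rose and 882 fell among those at 50 FPKM or more. Rises made up 57.9%, 43.4% and 38.7% of the calls in these 3 classes. With FPKM rebuilt on the reads in genes, 8889 genes rose and 4234 fell, so rises made up 67.7% of the calls instead of 46.5%. The median log2 fold change of all genes then moved from -0.03 to 0.13, and the shares of rises in the 3 classes were 73.3%, 67.5% and 54.5%. The rescalings fixed in advance moved the balance less, with 51.1% rises after a trimmed mean and 54.1% after quantile normalization. The 10 most abundant genes took 2.89 ± 0.175% of the reads in 'Bly114' stems and 2.09 ± 0.084% in WB stems (SD, n = 3 each), and the two-sided exact permutation p of 0.1 is the smallest that 3 against 3 allow. The fitted rise of MD11G1204100 rests on the pseudocount, with log2 fold changes of 8.57 and 11.04 at pseudocounts of 0.1 and 0.01, and the genotype tag of the WB stems reads wild type, although the source names give WB as the scion of the MB leaves too.

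In leaves, which carry the MB and wild-type tags, more genes differed than in stems. In MB leaves 6972 genes rose and 7598 fell, together 47.0% of those tested, with a median absolute log2 fold change of 0.74. Among changes of at least 4-fold, 655 genes rose and 378 fell, and 55 rose and 29 fell by at least 16-fold. MD11G1082600, which also led the rises in stems, rose from 22.1 ± 3.42 FPKM in wild-type leaves to 1143 ± 44.7 in MB leaves (SD, n = 3 each; log2 fold change 5.64, SE 0.24, limma adjusted p = 4.3e-09). MD11G1004100 rose from 1.64 ± 0.0956 to 130 ± 12.4 FPKM (log2 fold change 5.64, SE 0.13, limma adjusted p = 3.7e-11). MD01G1090900 fell from 525 ± 58.3 to 4.76 ± 0.862 FPKM (log2 fold change -6.52, SE 0.12, limma adjusted p = 2.6e-11), a 110.3-fold fall, and MD09G1161200 fell from 112 ± 9.61 to 1.0 ± 0.427 FPKM (log2 fold change -5.84, SE 0.16, limma adjusted p = 1.6e-10), a 112.2-fold fall. The libraries of both groups did not overlap for 17182 genes, 55.4% of those tested, where chance gives 10%.

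In leaves as well, rises were the larger share of calls among low genes. Of genes with a mean under 5 FPKM, 2234 rose and 1562 fell (58.9% rises), of those at 5 to 50 FPKM 3997 rose and 5210 fell (43.4%), and of those at 50 FPKM or more 741 rose and 826 fell (47.3%). With FPKM rebuilt on the reads in genes, 8561 genes rose and 5436 fell, so rises made up 61.2% of the calls instead of 47.9%. Their shares in the 3 classes were then 69.3%, 58.4% and 58.1%. After rescaling by a trimmed mean and after quantile normalization, rises made up 48.9% and 48.8% of the calls, close to the deposited scale. The 10 most abundant genes took 6.05 ± 0.461% of the reads in wild-type leaves and 4.60 ± 0.108% in MB leaves (SD, n = 3 each; two-sided exact permutation p = 0.1, the smallest possible here).

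**Figure D2:**
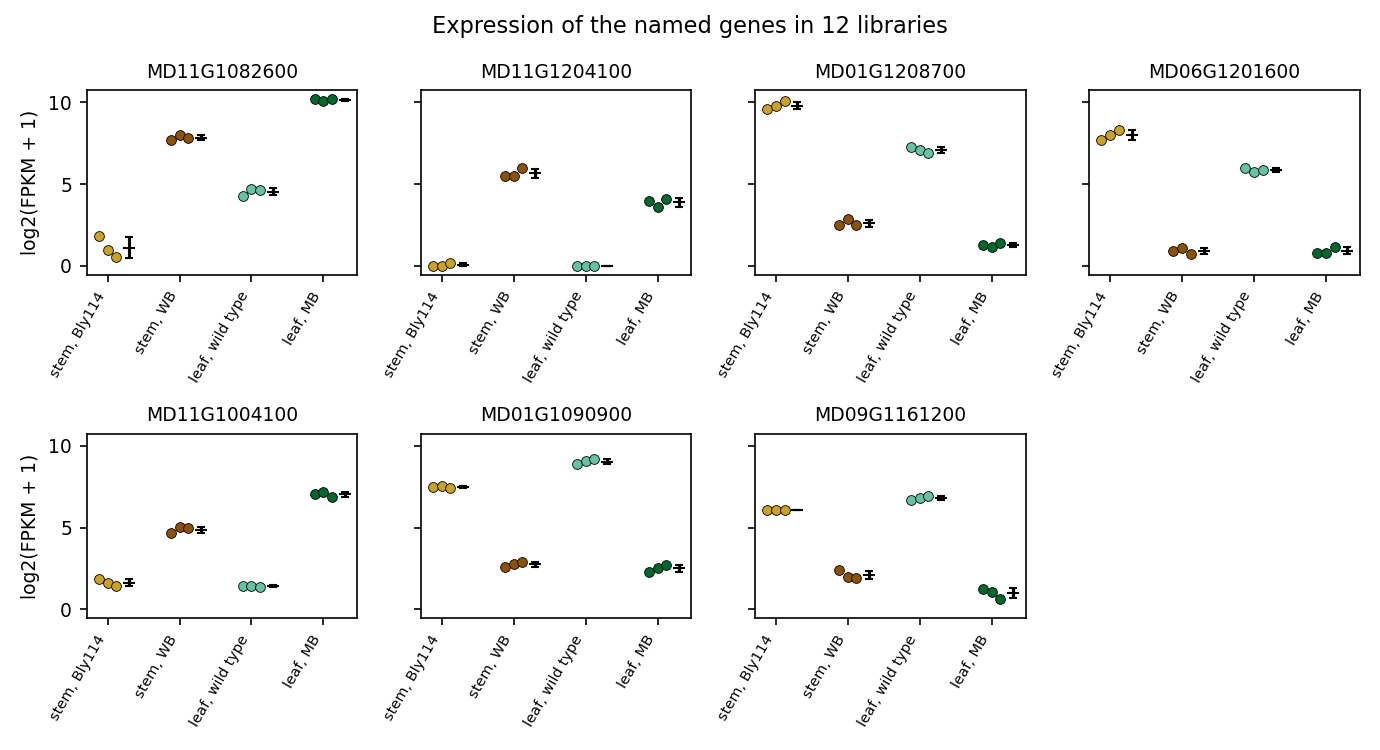
Expression of the 7 genes named for the stem and leaf comparisons, as log2(FPKM + 1) on the y axis, in the 4 groups on the x axis, with 1 point per library and, beside the points, the mean with its SD. MD11G1082600 averaged 1143 FPKM in MB leaves and 1.30 FPKM in 'Bly114' stems, and MD01G1208700 averaged 900 FPKM in 'Bly114' stems and 1.42 FPKM in MB leaves.

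Most genes that were called in both tissues changed in the same direction. The stem and leaf comparisons share no library, and 3716 genes rose in both and 3836 fell in both, where lists without any relation would share 1204.9 and 1510.7. These 7552 genes were 94.1% of all genes called in both tissues. The odds ratios were 15.5 for rises and 9.22 for falls in the one-sided Fisher's exact test, whose p-values were too small to be stored. Opposite directions were found for 119 genes that rose in stems and fell in leaves and 354 that fell in stems and rose in leaves, where unrelated lists would share 1313.1 and 1386.3. Both comparisons used a common estimate of the spread per gene, and abundant genes were called more often in both. The numbers given for unrelated lists may therefore be too low. Across genes, the stem and leaf log2 fold changes had a Pearson r of 0.67 and a Spearman rho of 0.61, and genes are not independent replicates. Changes of at least 4-fold in both tissues were shared by 147 genes that rose and 133 that fell, and of at least 16-fold by 8 and 10. With the libraries of each tissue fitted alone, 3458 genes rose in both and 3489 fell in both. With FPKM rebuilt on the reads in genes, 5542 rose in both and 2484 fell in both.

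The genes named for 1 tissue changed in the other as well. MD11G1204100 had no read in the wild-type leaf libraries and 13.8 ± 2.62 FPKM in MB leaves (SD, n = 3), at least 27.1-fold above the level that 3 reads per library would give. MD01G1208700 fell in leaves from 134 ± 16.8 to 1.42 ± 0.199 FPKM, and MD06G1201600 from 56.4 ± 4.93 to 0.885 ± 0.295 FPKM. MD11G1004100 rose in stems from 2.09 ± 0.452 to 28.4 ± 3.70 FPKM, MD01G1090900 fell there from 178 ± 5.10 to 5.73 ± 0.639 FPKM, and MD09G1161200 fell from 66.4 ± 1.11 to 3.28 ± 0.797 FPKM. All of these changes had a limma adjusted p of 3.7e-09 or less.

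**Figure D3:**
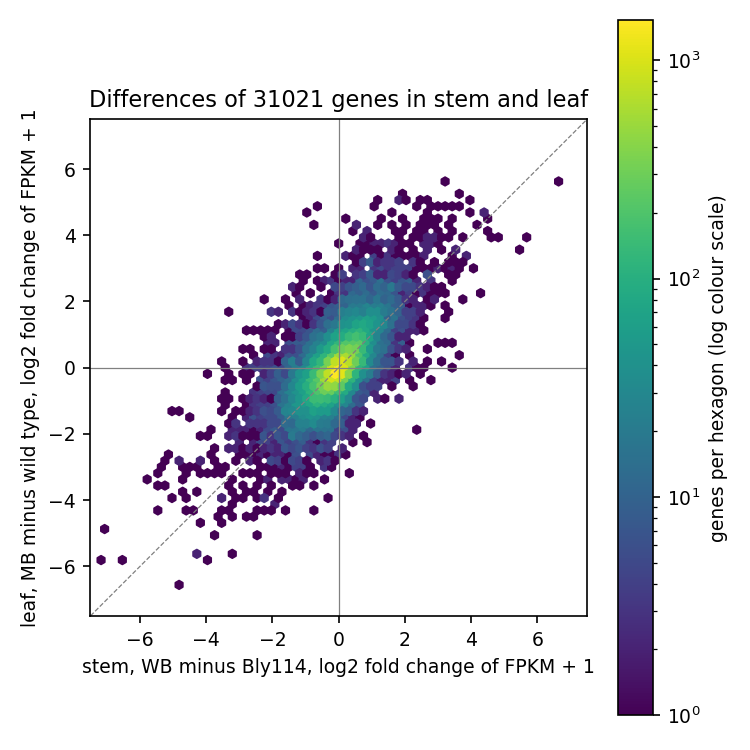
Log2 fold change of FPKM + 1 in stems (x axis, WB minus 'Bly114') against that in leaves (y axis, MB minus wild type) for the 31021 genes tested, with the number of genes in each hexagon on a log colour scale and the line of equal change dashed. The cloud rises from lower left to upper right, with a Pearson r of 0.67 across genes.

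The interaction asked which genes differed between MB and wild-type leaves by another amount than between WB and 'Bly114' stems. For 3329 genes the leaf difference lay above the stem difference, and for 2329 genes it lay below, together 18.2% of those tested. The size of this excess depended on the scaling. It was lost with FPKM rebuilt on the reads in genes (2986 above and 2978 below) and after quantile normalization (2826 and 2886). It remained after rescaling by a trimmed mean (3157 and 2694) and, on the deposited scale, at a fold of at least 2 (1685 and 761). Of the 7552 genes that changed in the same direction in both tissues, 1730 also differed in size. All 473 genes called in opposite directions passed the interaction test, which opposite calls from 1 model nearly ensure. Of the 6545 genes called in leaves and not in stems, 2284 passed the interaction test, and of the 3504 called in stems and not in leaves, 1093 did. MD10G1330600 rose in leaves from 5.34 ± 1.21 to 173 ± 8.29 FPKM and fell in stems from 11.1 ± 2.21 to 6.40 ± 0.600 FPKM (SD, n = 3 each; interaction 5.50, SE 0.21, limma adjusted p = 2.2e-07). MD00G1161400 rose in leaves from 3.71 ± 0.863 to 116 ± 28.0 FPKM, whereas its stem libraries held 2.65, 1.52 and 45.4 FPKM in 'Bly114' and 20.9, 0.872 and 0.515 FPKM in WB (interaction 5.55, SE 1.498, limma adjusted p = 0.023).

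Among genes whose leaf difference lay below the stem difference, MD14G1150400 fell in leaves from 25.2 ± 9.33 to 0.586 ± 0.179 FPKM and had 0.241 ± 0.278 and 0.0513 ± 0.0445 FPKM in 'Bly114' and WB stems (SD, n = 3 each; interaction -3.78, SE 0.32, limma adjusted p = 1.9e-05). MD16G1025800 rose in stems from 11.9 ± 3.69 to 61.8 ± 7.08 FPKM and held 36.3, 2.92 and 4.46 FPKM in the wild-type leaf libraries against 1.55 ± 1.21 FPKM in MB leaves (interaction -4.30, SE 0.93, limma adjusted p = 0.0071). The call of MD14G1150400 was lost with a pseudocount of 0.01 (adjusted p = 0.155) and with voom on the recovered reads (0.106), over a range that otherwise reached 0.0041. The call of MD00G1161400 was lost without WB stem library 2 (adjusted p = 0.055), without WB stem library 3 (0.060) and without 1 of the MB leaf libraries (0.052), against 0.0041 to 0.048 in its other alternatives. Its interaction was 4.24 without 'Bly114' stem library 3, 6.34 without 'Bly114' stem library 2, 6.78 without WB stem library 1 and 4.85 without WB stem library 3. That of MD16G1025800 was -3.30 without wild-type leaf library 1 and -4.92 without library 2. Without both wild-type leaf library 1 and 'Bly114' stem library 3, the interactions were 4.08 for MD00G1161400 and -3.03 for MD16G1025800.

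Wild-type leaves and 'Bly114' stems differed for more genes than the scions did within a tissue. Expression was higher in leaves for 9826 genes and lower for 9483, together 62.2% of those tested, and by at least 4-fold for 1473 and 1165. MD17G1250000 had 18.3 ± 8.70 FPKM in stems and 1805 ± 281 in leaves (SD, n = 3 each; log2 fold change 6.66, SE 0.28, limma adjusted p = 5.6e-09), and MD06G1100900 had 3.71 ± 3.45 and 326 ± 81.6 FPKM (6.35, SE 0.39, 5.2e-08). MD00G1187200 had 490 ± 174 FPKM in stems and 1.79 ± 0.456 in leaves (log2 fold change -7.40, SE 0.27, limma adjusted p = 2.3e-09), and MD09G1074600 had 589 ± 51.1 and 4.23 ± 5.31 FPKM (-7.29, SE 0.52, 1.8e-07). The wild-type leaf libraries held 10.4, 0.996 and 1.34 FPKM of MD09G1074600, and its log2 fold change was -8.09 without leaf library 1. The SD of the log2 fold changes over all genes was 1.13 for this comparison, 0.82 for MB against wild-type leaves and 0.67 for WB against 'Bly114' stems. With FPKM rebuilt on the reads in genes, 6334 genes were higher and 15195 lower in leaves, so 29.4% of the calls were higher instead of 50.9%. The median log2 fold change of all genes then moved from 0.00 to -0.31. After rescaling by a trimmed mean and after quantile normalization, 48.5% and 48.4% of the calls were higher.

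In receptacles, levels could be read for the 3 MB libraries only, and no difference was tested. At least 1 FPKM was reached by 25700 genes in all 3 libraries, 8492 genes were listed at 0 in all 3, and Pearson correlations across genes between the libraries were 0.980 to 0.987. MD11G1082600 stood at 102 ± 14.9 FPKM, MD01G1208700 at 11.2 ± 2.00, MD06G1201600 at 0.876 ± 0.102, MD01G1090900 at 12.5 ± 0.205 and MD09G1161200 at 0.339 ± 0.183 FPKM (SD, n = 3). MD11G1004100 stood at 5.18 ± 1.73 FPKM, and MD11G1204100 was listed at 0 in each receptacle library. The receptacle table was normalized separately from that of stems and leaves, so these levels are not comparable in size with those above.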

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

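The tests on gene length, on the wild-type tag of both stem groups and on genes 20 to 40 places apart, and the rescaling to reads in genes, were chosen after the results had been seen. What singled out the following results was a tested difference between tissues. The leaf difference between the scions lay above the stem difference for 3329 genes and below it for 2329. This balance became 2986 and 2978 on reads in genes, 2826 and 2886 after quantile normalization, and 3157 and 2694 after rescaling by a trimmed mean. Among genes that passed the interaction test, 119 rose in stems and fell in leaves, and 354 fell in stems and rose in leaves. Opposite calls nearly ensure a pass. The interaction was 5.55 for MD00G1161400, 5.50 for MD10G1330600, -4.30 for MD16G1025800 and -3.78 for MD14G1150400 on the log2 scale. After the effect common to both tissues was subtracted, the real grouping called 5639 genes. Of 100 drawn splits (of 200 possible), 1 reached that count, which was the real one, and the highest other split called 1 gene. This argues against chance assignment of these libraries for the interaction, with 1 of 100 the smallest share that the draws allow. Mixed splits carry group differences in their spread, which lowers their counts, and the splits concern libraries, not plants. For the 11529 genes of the stem comparison, the 14570 of the leaf comparison and the 19309 of leaf against stem, 10 splits of 6 libraries are too few for a share under 0.05, and the highest other split called 0 genes in each.

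Many genes differed between the scions, and 7552 did so in the same direction in stem and leaf. For these genes as a set, the authors' scaling is argued against as the whole cause. On reads in genes, 82.0% were still called the same way, and after quantile normalization 88.5%. The falls were less stable on reads in genes, where 2484 genes fell in both tissues, against 3836 on the deposited scale. At most 2484 of those falls can have stayed, and scaling remains open as a cause of the others. The shared rises numbered 5542 there, against 3716. Gene length is argued against too, because 94.5% of the 7552 genes were still called after each library's trend with length had been removed. The correlation of 0.67 across genes between stem and leaf differences shows that WB stems departed from 'Bly114' much as MB leaves departed from wild type. It restates the pattern, so it cannot decide whether both stem groups are wild type, as their genotype tag reads. A date or batch shared by WB stems and MB leaves could give it too, and no label gives either. Among the labels, the source names, with WB as the scion of the MB leaves too, speak against the tag. The titles go the same way, starting with W for 'Bly114' stems and wild-type leaves and with M for WB stems and MB leaves. A difference between the mutant and its parent may account for the pattern, as a hypothesis that came from these libraries and was not tested.

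Wild-type leaf library 1 lay nearer the stems than libraries 2 and 3, and 'Bly114' stem libraries 1 and 2 lay nearer the leaves than library 3. Stem RNA in leaf library 1 should give stem-preferential genes 1 common share, but only 17.3% of 173 such genes lay within 2-fold of their median share of 2.62%, and the implied shares of the 5 most abundant were 0.8, 2, -1, 1.6 and 0.2%, which argues against it. For leaf RNA in stem libraries 1 and 2, 57.2% of 446 leaf-preferential genes lay within 2-fold of a median share of 4.73% (quartiles 2.21 and 7.73%), between the bounds set in advance. The implied shares of the 5 most abundant of these genes were 9.5, 4.2, 7.3, 7.8 and 8.5%, which goes with leaf RNA, but the share of genes missed the bound set for it, so leaf RNA and another difference between these libraries cannot be told apart. No biological explanation was tested, since the labels give no difference between libraries of a group.

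Genes adjacent by identifier among those tested differed together between the scions, with a correlation of 0.154 over 30059 pairs against at most 0.018 in 1000 shuffled orders. Untested genes may lie between the members of a pair, and between genes a given number of places apart. The 11883 pairs with lengths over 2-fold apart still gave 0.117, above the 0.036 reached by shuffled orders. This argues against reads shared between near-identical copies of like length as the whole cause. Copies of unlike length could share reads too, and no sequences were compared. The 3136 pairs with lengths within 1.1-fold gave 0.235, so shared reads may add to the correlation. Copy-number changes of long segments are argued against as the main cause of this correlation by a mean correlation of -0.0025 at 20 to 40 places. An average over all genes could miss a change of 1 segment, so such a change is not excluded. The contrast of leaf with stem gave 0.143 for adjacent genes, so the pattern is not particular to the scions, and no biological explanation was tested.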

How the results depend on the processing

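The voom fits, FPKM on reads in genes and the fit without 'Bly114' stem library 3 and wild-type leaf library 1 were chosen after the data had been seen. Requiring a fold of at least 2 reduced the calls to 3057 in stems, 4738 in leaves, 2446 for the interaction, 8528 for leaf against stem and 1803 called the same way in both tissues, because fewer genes meet both criteria. The other alternatives stayed within 1.5 times of the reported counts, 13 of 14 in stems (highest 13123), 12 of 13 in leaves (15158), 11 of 12 for the interaction (6622), 12 of 13 for leaf against stem (21529) and 4 of 5 for the shared calls (8026). Without the 2 libraries the counts were 11433, 15158, 6622, 18751 and 7587. Leaving out 1 library at a time gave 9466 to 10222 calls in stems, 12746 to 14359 in leaves, 4550 to 6549 for the interaction, 17479 to 19496 for leaf against stem and 6545 to 7629 shared calls. Of 312 values of named genes under alternatives, 307 kept their direction and their call, 5 lost the call and 0 reversed. The lost calls were the interactions of MD14G1150400 (-4.12 with a pseudocount of 0.01, -4.12 with voom) and MD00G1161400 (5.01, 4.85 and 5.39 without a library), and the cause was not tested. A pseudocount of 0.01 moved the log2 fold change to 7.77 for MD11G1082600, 11.04 for MD11G1204100 and -8.23 for MD06G1201600 in stems, to 6.305 for MD11G1004100 and -6.89 for MD09G1161200 in leaves, to 6.38 for MD00G1161400 and -5.12 for MD16G1025800 in the interaction, and to -8.05 for MD00G1187200 and -7.93 for MD09G1074600 in leaf against stem. With voom, the first 8 of these were 7.73, 9.14, -8.24, 6.29, -6.88, 6.31, -5.11 and -8.01. Quantile normalization moved MD17G1250000 to 5.97 in leaf against stem. With a replicate block, 11174 genes were called in stems, 10842 of them among the reported calls, and 19248 for leaf against stem. In the groups that could be examined, the numbers gave no sign of pairing. Same-numbered deviations correlated at 0.042, -0.136 and 0.078 between the stem groups and at -0.172, -0.064 and -0.101 between 'Bly114' stems and wild-type leaves. Not every library correlated best with its own number. With 3 libraries per group, whose deviations are tied to each other, such values cannot exclude a pairing. No paired analysis was possible for leaves and the interaction because the MB leaf columns could not be tied to single samples, so whether the numbers that the source names give to WB stems and MB leaves pair them was not examined. The alternatives for the gene lists and for the receptacle comparison were not run, as neither result could be made. Depth limits genes near 1 FPKM, where a value rests on 17.3 to 29.3 reads at the median length.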

Other observations

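The gene groups, the genes without reads and the receptacle levels below were chosen after the data had been seen. Genes were grouped by tissue from the contrast of leaf with stem averaged over both scions, at an adjusted p under 0.05 and a fold of at least 4, so the groups come from the same libraries as the scion differences. Of 1468 leaf-preferential genes, 370 rose, 429 fell and 669 were not called in WB stems, and 414 rose, 506 fell and 548 were not called in MB leaves. Of 932 stem-preferential genes, 105 rose, 261 fell and 566 were not called in WB stems, and 119 rose, 152 fell and 661 were not called in MB leaves. Against other genes, the stem-preferential group was lower in WB stems in limma's camera with its preset correlation (median log2 fold change -0.33, adjusted p = 0.0063), and this call was lost with an estimated correlation (adjusted p = 0.959). The other 3 tests did not pass with the preset correlation, with adjusted p of 0.72 for leaf-preferential genes in stems and 0.837 for both groups in leaves.

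Without 'Bly114' stem library 3 and wild-type leaf library 1, which stood apart from their groups, 356 of 1434 leaf-preferential genes rose and 653 fell in WB stems. This group then also passed camera's test with the preset correlation (adjusted p = 0.0028), but not with an estimated correlation (adjusted p = 0.454). The 'Bly114' stem libraries that remain in this fit are those in which leaf RNA could not be excluded above. Leaf RNA in them would by itself make leaf-preferential genes appear to fall in WB stems. The falls of this group in WB stems therefore carry no conclusion on the scions. Of 1042 stem-preferential genes, 122 rose and 303 fell in WB stems (adjusted p = 0.0065 with the preset correlation and 0.454 with an estimated correlation). In MB leaves, 420 leaf-preferential genes rose and 666 fell (adjusted p = 0.0758 with the preset correlation). The balance of the stem-preferential group in MB leaves turned, from a median log2 fold change of -0.03 with all libraries to 0.09 with 197 genes that rose and 145 that fell, and passed camera's test in neither case (adjusted p = 0.837 and 0.142 with the preset correlation).

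A search for genes read in the libraries of only 1 kind of scion found 3 genes without a read in the 6 'Bly114' and wild-type libraries and at 2 FPKM or more in all 6 WB and MB libraries, and 0 genes the other way round. MD08G1062300 had 23.8 ± 3.31 FPKM in WB stems and 16.1 ± 4.94 in MB leaves (SD, n = 3 each), at least 44.5-fold and 21.9-fold above the level of 3 reads per library. MD05G1025100 had 4.04 ± 0.546 and 2.54 ± 0.244 FPKM, at least 40.3-fold and 18.4-fold above that level. MD03G1239500 had 4.41 ± 0.875 and 9.82 ± 0.748 FPKM, at least 8.41-fold and 13.6-fold above it. All 3 genes were listed at 0 in the 3 MB receptacle libraries, whose table was normalized separately.

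Of the 133 genes that fell by at least 4-fold in both stems and leaves, 114 (85.7%) had a receptacle level nearer the mean of the WB and MB libraries than that of the 'Bly114' and wild-type libraries. Of the 147 that rose by at least 4-fold in both, 57 (38.8%) did. The median log2(FPKM + 1) of the genes that fell was 5.53 in 'Bly114' and wild-type libraries, 2.37 in WB and MB libraries and 3.09 in MB receptacles, and that of the genes that rose was 1.91, 5.003 and 3.03. These are values across tables normalized separately, without wild-type receptacles beside them, and no test was made. The levels are not comparable in size, so these counts may reflect the scaling or the tissue and carry no conclusion on the scions.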
